A study of Mus musculus with 8 samples.

How the data were processed

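Liver RNA of adult male mice was measured on the 8 sections of 1 Illumina BeadChip, with 1 array per labelled sample. According to the series title the mice were ob/ob, a strain that makes no functional leptin, and the treatment lasted 12 days. Samples were grouped by the leptin dose in their labels: 3 arrays at 0 ng/hr (controls, replicates 1 to 3), 2 arrays at 12.5 ng/hr (replicates 4 and 5) and 3 arrays at 25 ng/hr (replicates 6 to 8). The agent field of the labels contradicts this grouping, since it reads untreated for the 25 ng/hr arrays and leptin for the 0 ng/hr arrays. Title, source and dose fields give the same groups, and these were used. Group order follows the order of positions on the BeadChip, so a smooth trend along the chip and the dose run together.

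Per the labels' protocols, RNA was extracted with Trizol from flash-frozen livers and biotin-labelled cRNA was made with a kit for Illumina arrays. The scanner software, its settings and the genome build are not given in the sources used here. The first table the authors deposited holds 25697 probes with an average signal per array, an intensity on a linear scale before any scaling between arrays, and a detection p-value per probe and array. In a second deposited table the authors multiplied every intensity of an array by a single factor, between 0.93 and 1.08, so that all arrays have a mean of 493. This table also gives the authors' mean intensity per group and the ratio of these means for each pair of groups. Its header assigns 3 arrays to the middle group, while the deposited means equal those of the 2 arrays labelled 12.5 ng/hr. The value table of the series matrix holds the same scaled intensities, on a linear scale, with no centring and no ratio. The column medians of the scaled intensities lay between 68.4 and 74.2.

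The unscaled intensities were background-corrected, quantile-normalized and put on a log2 scale with neqc of limma version 3.58.1 in R version 4.3.3, which estimates the background from the detection p-values (offset 16). Features needed a detection p-value under 0.05 on at least 2 arrays, and of several probes of a gene the one with the highest mean log2 signal was kept. This left 10118 features, 9864 of them with a current gene symbol. Symbols came from the deposited transcript definitions and names, updated with an NCBI gene table of assembly GRCm38.p6 that was used for names only. Of all probes, 659 matched no current symbol and kept the name in the file. Probes of near-identical paralogs, such as the major urinary protein and histone genes, can bind each other's transcripts.

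All 8 arrays entered 1 limma fit with 3 group means, so that the 12.5 ng/hr group borrows its spread from the others. Moderated tests (lmFit, eBayes) were run for 25 minus 0, 12.5 minus 0, 25 minus 12.5 ng/hr and for the mean of both doses minus 0 ng/hr, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene is from this fit unless another test is named. Errors of fold changes are standard errors (SE) of that fit. Where a gene's signal was not above background on any array of the dimmer group, the fold is given as a lower bound. The bound sets the brighter group's mean against the mean of the lowest signal detected per array, or of the dim probe's own signal where that was higher.

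A total of 28 gene lists, 19 pathways and 9 cell types, was fixed before the data were examined, with 431 entries, 349 of them tested. Each list was tested in 3 contrasts with limma's camera at a preset correlation of 0.01 and adjusted over all 84 tests. The same tests with an estimated correlation and with fry were alternatives. The rule for named genes was fixed at the same time. It took Igfbp2, Lepr and Scd1 always, the 10 largest rises and 10 largest falls per contrast among genes past the threshold whose groups did not overlap, filled up to 5 by smallest p where fewer passed, and up to 4 members per list. Some results that the rule selects are not reported here.

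The fit was tested on simulated data with 200 changed genes among 10118. Variances were drawn from the prior that the fit had estimated, and normal noise was independent between genes and arrays. The shares recovered therefore hold under the fit's own assumptions and may be lower on real arrays. For 25 minus 0 ng/hr it recovered 34% of changes of 0.5 on the log2 scale and 90% of changes of 1, with 5 false calls. For 12.5 minus 0 ng/hr it recovered 10% and 88%, with 7 false calls, and for 25 minus 12.5 ng/hr 22% and 80%, with 8 false calls. Alternatives covered median scaling, no background correction, the authors' scaled intensities, both looser and stricter detection filters, every probe as a feature, another variance prior, array weights, fits of fewer groups and leaving out each array in turn. Figures were drawn with matplotlib version 3.10.9 in Python version 3.11.15. Chromosomes are those of the deposited annotation, and no coordinates are given because its build is not named.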

Results

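Gene expression was measured in the livers of adult male ob/ob mice that received leptin at 0, 12.5 or 25 ng/hr for 12 days, on 3, 2 and 3 arrays. Groups follow the dose in the labels, whose agent field assigns leptin and no treatment the other way round, so every direction rests on the dose being right. Between 12094 and 12783 probes per array (47.1% to 49.7%) were above background, and mean intensities before scaling lay between 456 and 532. Log2 values of arrays of the same group correlated across features with r from 0.988 to 0.993, and those of different groups with r from 0.981 to 0.993. The first principal component, with 30.5% of the variance, separated the 25 ng/hr arrays from the controls. Each label describes an adult male mouse, but the labels do not state that each array holds a separate animal, and otherwise p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

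The comparison of 25 with 0 ng/hr asks what a low dose of leptin changed in the liver of mice that lack the hormone. In limma's test 90 of 10118 features passed an adjusted p of 0.05, 63 higher and 27 lower at 25 ng/hr, and 24 of them changed more than 2-fold. Among the genes that passed, the largest rise was that of Mup4, a major urinary protein gene, which was 7.51-fold higher (log2 2.91, SE 0.39, adjusted p = 0.0247, n = 3 and 3). Mup5, of the same family, rose 5.25-fold (log2 2.39, SE 0.42, adjusted p = 0.0433), and both lie on chromosome 4. C8b and C8a, which encode subunits of the terminal complement complex, rose 3.94-fold (log2 1.98, SE 0.30) and 3.24-fold (log2 1.70, SE 0.30). The carboxylesterase gene Ces3b rose 3.82-fold, Nrep, a gene first described in regenerating nerve, 3.95-fold and the sulfotransferase gene Sult2a8 3.02-fold. Gbp2b, an interferon-inducible guanylate-binding protein gene, rose 3.30-fold (log2 1.72, SE 0.16, adjusted p = 0.0175), with 1 of 3 control arrays above background. Elovl3, a fatty acid elongase gene, rose 2.53-fold, and Folr2, which encodes a folate receptor of macrophages, rose 2.51-fold. With the authors' scaled intensities, which have no background correction, the log2 values of Gbp2b, Elovl3 and Folr2 were 0.89, 0.81 and 0.85, and all 3 kept their calls.

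The largest fall among the genes that passed was that of Fndc10, 3.40-fold (log2 -1.76, SE 0.18, adjusted p = 0.0175). Ccdc120 fell 2.86-fold, the membrane protein gene Emp1 2.78-fold and Smpd3, which encodes a neutral sphingomyelinase, 2.63-fold. Col6a1, a collagen VI chain gene, fell 2.18-fold (log2 -1.12, SE 0.13, adjusted p = 0.0175), and Cdkn1c, an inhibitor of cyclin-dependent kinases, fell 2.16-fold (log2 -1.11, SE 0.13, adjusted p = 0.0175). Acat1, a thiolase gene of ketone body metabolism, the creatine transporter gene Slc6a8, Lrfn3 and the ubiquitin ligase gene Trim2 fell by 1.98-, 1.94-, 1.85- and 1.75-fold.

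Igfbp2, which encodes an insulin-like growth factor binding protein secreted by the liver, missed the threshold over all genes with the probe kept for it. Its mean log2 signal was 6.33 ± 0.90 (SD, n = 3) in the controls, 7.13 ± 1.36 (SD, n = 2) at 12.5 ng/hr and 9.33 ± 0.61 (SD, n = 3) at 25 ng/hr. The estimate for 25 minus 0 ng/hr was 8.04-fold (log2 3.01, SE 0.57, adjusted p = 0.0529 in limma's test). Every 25 ng/hr array lay above every control, and the ratio of the authors' deposited group means was 5.28. Another Igfbp2 probe gave a log2 difference of 2.79 (SE 0.44). In limma's fit of all detected probes its unadjusted p was 0.000116, against 0.000409 for the kept probe. Both Igfbp2 probes were among the 118 of 13760 that passed in that fit. The miss may thus depend on the rule that keeps 1 probe per gene. In the list of IGF axis and insulin signalling genes, which was not called, Igfbp2 passed when adjusted over the list alone (0.00777). Over the 17 alternatives, which include leaving out each array in turn, the adjusted p of Igfbp2 ran from 0.0169 to 0.184 and passed the threshold in 7. Lepr, the leptin receptor gene, was not above background on any array of either leptin dose, and its adjusted p was 0.508 at 25 ng/hr. Scd1, the hepatic stearoyl-CoA desaturase gene, had a log2 difference of -0.17 (SE 0.15, adjusted p = 0.621).

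**Figure D1:**
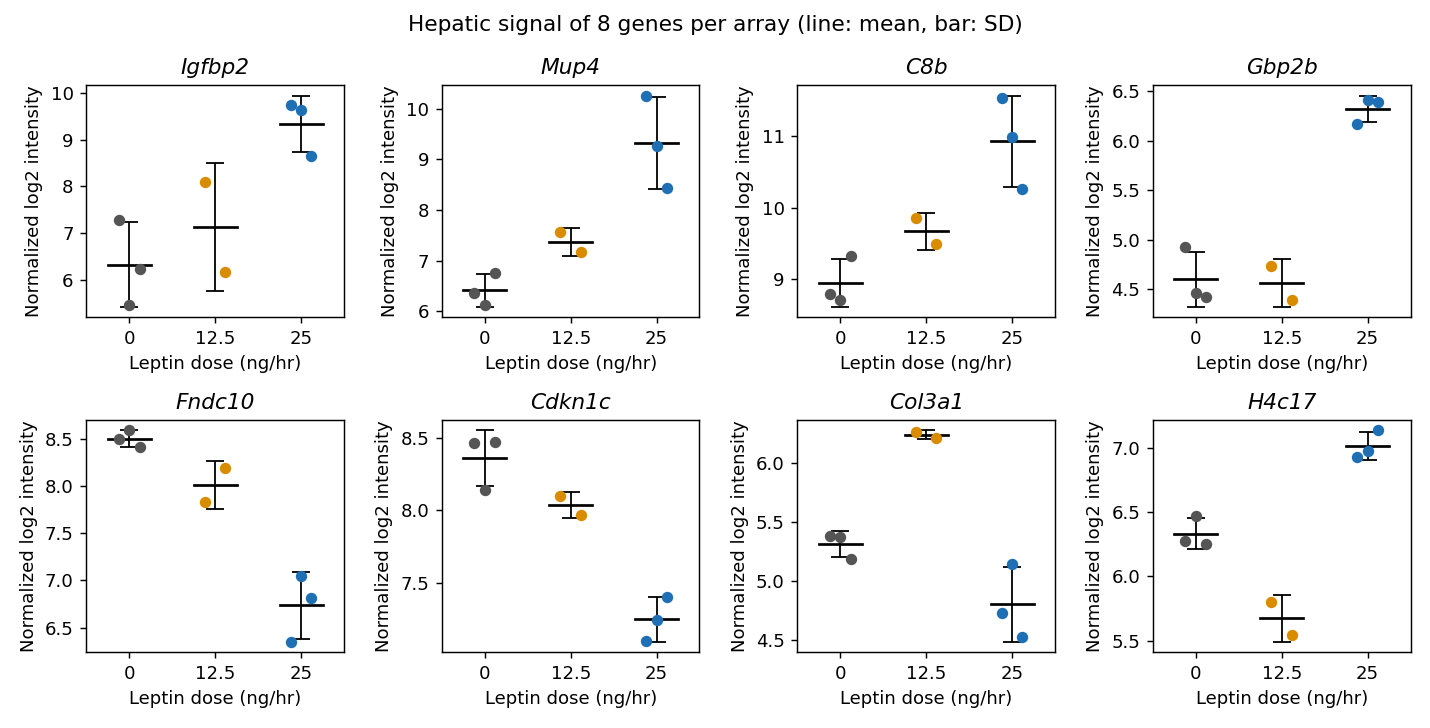
Normalized log2 intensity of 8 genes (vertical axes) against the leptin dose in ng/hr (horizontal axes), with 1 point per array, lines at group means and bars of 1 SD, n = 3, 2 and 3. Igfbp2, Mup4, C8b and Gbp2b are highest at 25 ng/hr, Fndc10 and Cdkn1c lowest, and the 12.5 ng/hr arrays lie above the controls for Col3a1 and below them for H4c17.

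Among the gene lists, camera called 6 of 28 at 25 minus 0 ng/hr, and none of these calls held with an estimated correlation. Genes that are more active in male than in female mouse liver were higher: 12 of 13 tested members lay above 0, with a median log2 difference of 0.72 (adjusted p = 6.69e-07; adjusted p = 0.811 with an estimated correlation). Of this list Mup4, Elovl3 and Ugt2b1, a glucuronosyltransferase gene (log2 0.72, SE 0.11), passed over all genes, and 7 passed when adjusted over the list alone. The complement gene C6 had a log2 difference of 2.04 (SE 0.38, adjusted p = 0.0529 over all genes, 0.00165 adjusted over the list alone). The female-biased list was lower, with a median of -0.85 over 10 members (adjusted p = 0.0313; adjusted p = 0.811 with an estimated correlation), and none of its members passed over all genes or adjusted over the list alone. Its call was lost without 25 ng/hr replicate 6 (median -0.39, adjusted p = 0.316) or control replicate 2 (adjusted p = 0.107), with median scaling (0.0786) and with detection on all arrays (0.0577).

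Markers of macrophages and Kupffer cells, the resident macrophages of the liver, were higher at 25 ng/hr, with a median log2 difference of 0.56 over 11 members (adjusted p = 0.000103; adjusted p = 0.709 with an estimated correlation). Adgre1 (log2 0.95, SE 0.15), Clec4f (log2 0.83, SE 0.13), Vsig4 (log2 0.58, SE 0.09) and the receptor gene Csf1r (log2 0.56, SE 0.10) rose over all genes tested, and 8 members were higher when adjusted over the list alone. Gpnmb, a marker of lipid-associated macrophages above background on 2 of 3 arrays at 25 ng/hr, went the other way (log2 -2.18, SE 0.74, adjusted p = 0.187 over all genes, 0.0222 adjusted over the list alone), and the list's mean of 0.23 was below its median. Folr2, named above, is also a macrophage gene. With fry, another list test, this list had an adjusted p of 0.0386, and the other 5 called lists did not pass.

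Stellate cell and fibroblast markers were lower, with a median of -0.59 over 10 members (adjusted p = 0.0034; adjusted p = 0.811 with an estimated correlation). No member passed over all genes, and 5 passed when adjusted over the list alone, led by the proteoglycan gene Lum (log2 -0.83, SE 0.20). The call was lost when detection on all arrays was required (adjusted p = 0.135). Control replicate 1 had a log2 signal of 12.10 for the smooth muscle actin gene Acta2, against 7.30 to 9.05 on the other 7 arrays, and without that replicate the median of the list was -0.34 (adjusted p = 0.0314). Genes of the ER stress response were higher by a median of 0.19 over 18 members (adjusted p = 0.0103; adjusted p = 0.811 with an estimated correlation), and the disulfide isomerase gene Pdia6 rose over all genes (log2 0.75, SE 0.11, adjusted p = 0.0284). Adjusted over the list alone, 2 members of that list passed, Pdia6 and Pdia3. Glycolysis and pentose phosphate genes were lower by a median of 0.21 in size (log2 -0.21 over 15 members, adjusted p = 0.0313; adjusted p = 0.811 with an estimated correlation). None of these passed over all genes, and Pfkl, a liver phosphofructokinase gene, passed when adjusted over the list alone (log2 -0.42, SE 0.10). The glycolysis call was lost without control replicate 2 (adjusted p = 0.123) or 25 ng/hr replicate 6 (0.0905) or 7 (0.0897), and with median scaling (0.0732).

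The other 22 lists were not called at 25 minus 0 ng/hr (adjusted p from 0.0731 to 0.932). They covered fatty acid and sterol synthesis, fatty acid oxidation, lipid droplets, gluconeogenesis, the IGF axis, leptin and JAK-STAT signalling, bile acids, lipoproteins, xenobiotic metabolism, the acute phase, the respiratory chain, amino acid catabolism, the cell cycle, the circadian clock and 7 cell types. Single members passed when adjusted over their list alone. Among these were Cyp2b10, a drug-metabolising cytochrome gene (log2 -1.53, SE 0.35, 0.0194), Apom, an apolipoprotein gene (log2 0.77, SE 0.15, 0.0101), and the clock genes Dbp (log2 0.59, SE 0.14, 0.0235) and Arntl (log2 -0.57, SE 0.14, 0.0235; above background on 1 of 3 arrays at 25 ng/hr). Endothelial markers had a median of 0.01 over 9 members, with Clec4g higher and Vwf lower when adjusted over the list alone.

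**Figure D2:**
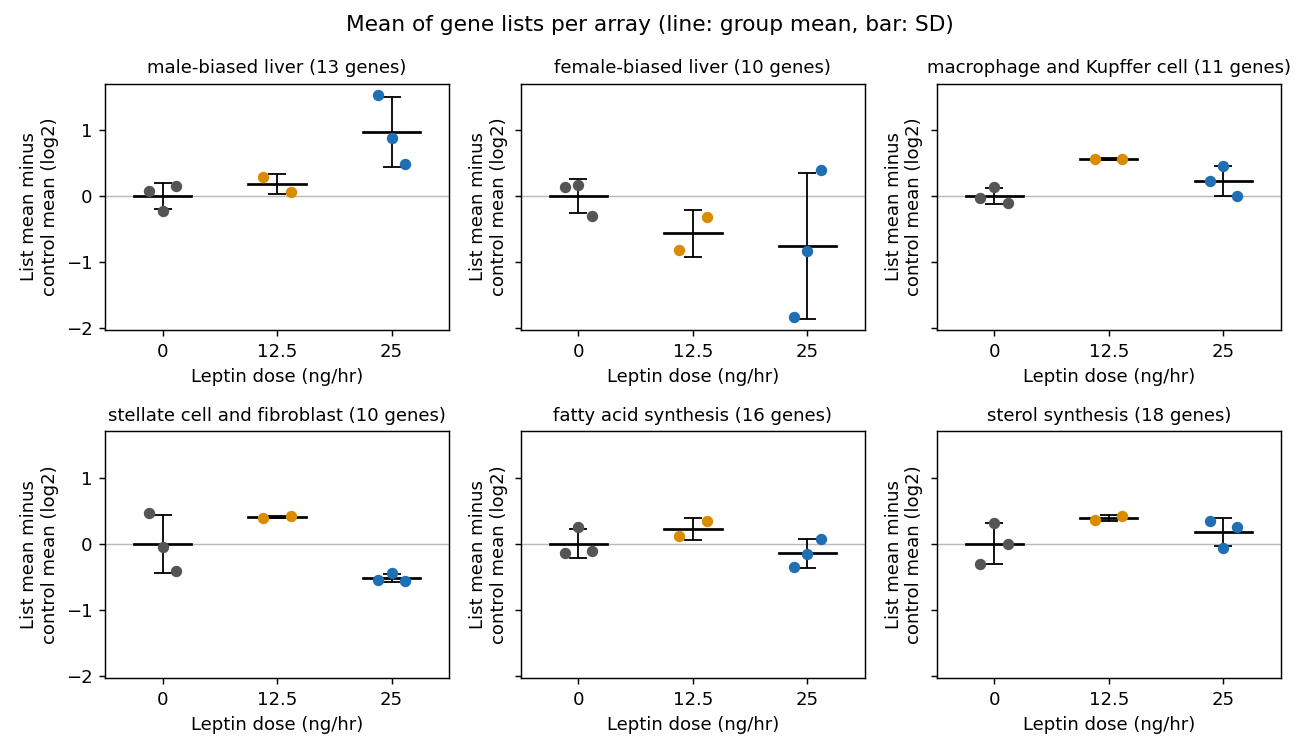
Mean log2 signal of 6 gene lists per array minus the mean of the controls (vertical axes) against leptin dose in ng/hr (horizontal axes), with 1 point per array, lines at group means and bars of 1 SD, n = 3, 2 and 3. The male-biased list lies between 0.49 and 1.53 on the 25 ng/hr arrays, while the female-biased list spreads from -1.83 to 0.39 on the same arrays.

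The count of 90 changed when single arrays were left out, those of the 12.5 ng/hr group included. It was 30, 0 and 6 without control replicate 1, 2 or 3, 15 without either 12.5 ng/hr array, 0 and 3 without 25 ng/hr replicate 6 or 7, and 131 without replicate 8, and it ran from 15 (only the groups compared in the fit) to 242 (a prior with a trend) over the other settings. Median scaling gave 35 genes, 20 higher and 15 lower.

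The comparison of 12.5 with 0 ng/hr asks which genes respond at the lower dose. No feature passed in limma's test, while 1164 had an unadjusted p under 0.05, where 505.9 were expected on average by chance. Genes vary together, which makes such counts spread widely, so this excess alone does not show an effect. The genes with the smallest p, none of which passed, were led on the higher side by Ly86, an accessory protein gene of immune cells (log2 0.94, SE 0.11, adjusted p = 0.0827, n = 2 and 3). Beside it stood Capn6 (log2 0.78, SE 0.10), Kctd12 (log2 0.87, SE 0.11), the interferon-inducible gene Trim30a (at least 1.84-fold, since no control array was above background) and the water channel gene Aqp8 (log2 0.81, SE 0.11), all at an adjusted p of 0.0827. On the lower side stood Aph1a, Rgs4, a regulator of G protein signalling (log2 -1.05, SE 0.17), the metallothionein gene Mt1 (log2 -0.68, SE 0.11), the mitochondrial calcium uniporter gene Mcu and Fam149b, with adjusted p from 0.128 to 0.141. Without background correction the log2 values of Capn6, Kctd12 and Rgs4 were 0.42, 0.55 and -0.61, and the bound of Trim30a holds for background-corrected values only. Igfbp2 had a log2 difference of 0.81 (SE 0.63, adjusted p = 0.684), which was -0.16 without 12.5 ng/hr replicate 4 and 1.76 without replicate 5, and Scd1 of 0.14 (SE 0.17). Lepr, not above background at 12.5 ng/hr, was at least 1.01-fold lower there without passing (adjusted p = 0.485).

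Of the lists, 7 were called at 12.5 minus 0 ng/hr, none of them with an estimated correlation. With fry the macrophage and Kupffer cell list had an adjusted p of 0.0386, and the other called lists did not pass. Macrophage and Kupffer cell markers were higher by a median of 0.59 (10 of 11 members above 0, adjusted p = 6.69e-07; adjusted p = 0.464 with an estimated correlation), and 8 members passed when adjusted over the list alone, among them Csf1r (log2 0.59, SE 0.11), Vsig4 and Adgre1. Sterol synthesis genes were higher by a median of 0.33 (17 of 18 members above 0, adjusted p = 4.93e-05; adjusted p = 0.811 with an estimated correlation), but no member passed even when adjusted over the list alone. Without control replicate 1 the median was 0.19. The largest of its leading differences was that of Fdps, a farnesyl diphosphate synthase gene (log2 0.90, SE 0.26). Fatty acid synthesis genes were higher by a median of 0.14 (14 of 16 members above 0, adjusted p = 0.0107; adjusted p = 0.811 with an estimated correlation). Adjusted over the list alone, Srebf1, which encodes a lipogenic transcription factor (log2 0.72, SE 0.16), and the desaturase genes Fads1 and Fads2 passed. The median of this list was 0.06, 0.30 and 0.08 without control replicate 1, 2 or 3 and 0.36 without 12.5 ng/hr replicate 4.

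Stellate cell and fibroblast markers were higher at 12.5 ng/hr by a median of 0.58 over 10 members (adjusted p = 0.000421; adjusted p = 0.811 with an estimated correlation). Adjusted over the list alone, Col1a1 (log2 1.43, SE 0.29; 2 of 3 control arrays above background), Col3a1 (log2 0.93, SE 0.17), Col1a2 and Reln passed, and none did over all genes. Without background correction Col1a1 and Col3a1 had log2 values of 0.84 and 0.52. With detection required on all arrays this call too was lost (adjusted p = 0.154). Lower lists were amino acid catabolism and the urea cycle (median -0.18, adjusted p = 0.0034), xenobiotic metabolism (median -0.19, adjusted p = 0.00361) and gluconeogenesis (median -0.23, adjusted p = 0.0127), each with adjusted p = 0.811 with an estimated correlation. No member of these passed over all genes or adjusted over the list alone. Leading members were the serine dehydratase gene Sds (log2 -0.65, SE 0.19), Cyp2b10 (log2 -1.31, SE 0.39) and Pck1, a gene of gluconeogenesis (log2 -0.63, SE 0.21). The amino acid catabolism median was -0.30 without control replicate 2. Without 12.5 ng/hr replicate 5 the calls of fatty acid synthesis, gluconeogenesis and amino acid catabolism were lost (adjusted p = 0.232, 0.0901 and 0.0886), and without control replicate 3 those of fatty acid synthesis and gluconeogenesis (0.0630 and 0.0517). The remaining 21 lists were not called (adjusted p from 0.101 to 0.925). Among their members, Pltp, a phospholipid transfer protein gene (log2 1.38, SE 0.25), the osteopontin gene Spp1 (log2 1.04, SE 0.27) and G0s2, an inhibitor of lipolysis (log2 0.69, SE 0.14), passed when adjusted over their list alone. The count of 0 became 9 without background correction, 10 with the authors' scaled intensities and 35 with a trended prior, and it was 2 without control replicate 2.

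The test of 25 minus 12.5 ng/hr is the only one of a difference between the doses. In it 43 features passed in limma's test, 12 higher and 31 lower at 25 ng/hr. Col1a1, a chain of type I collagen, was at least 3.52-fold lower at 25 ng/hr, where no array was above background (adjusted p = 0.0248, n = 3 and 2). Col3a1 was 2.73-fold lower (log2 -1.45, SE 0.17, adjusted p = 0.0169), with 1 of 3 arrays at 25 ng/hr above background, Col6a1 2.76-fold, Lum 2.61-fold and Loxl1, which crosslinks elastic fibres, 2.55-fold. The smallest adjusted p was that of Capn6, a calpain family gene at least 2.26-fold lower at 25 ng/hr (adjusted p = 0.0028). Emp1 (log2 -2.01, SE 0.30), Ccdc3 (log2 -1.43, SE 0.13), Bhlhb9 (log2 -1.28, SE 0.19) and the aldo-keto reductase gene Akr1c18 (at least 2.14-fold) were also lower. Without background correction the log2 values of Col3a1 and Loxl1 were -0.76 and -0.87. The bounds of Col1a1, Capn6 and Akr1c18 hold for background-corrected values only, since the uncorrected differences were smaller than these bounds, and all 5 genes kept their calls without the correction.

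Higher at 25 than at 12.5 ng/hr were Gbp2b (at least 2.75-fold, adjusted p = 0.0082) and the chemokine gene Cxcl13 (at least 1.80-fold, adjusted p = 0.0265), both not above background at 12.5 ng/hr. The H4 histone genes H4c17 (log2 1.34, SE 0.13, adjusted p = 0.0082), H4c12 (log2 1.08, SE 0.14), H4c8 (log2 0.93, SE 0.12) and H4c11 (log2 0.88, SE 0.14) were higher too, and of these H4c8 and H4c17 also passed at 25 minus 0 ng/hr (log2 0.72 and 0.68, adjusted p = 0.0287 and 0.0381). They are near-identical paralogs, and their probes can share signal. With the authors' scaled intensities H4c17, H4c12 and H4c11 had log2 values of 0.84, 0.69 and 0.58. The bounds of Gbp2b and Cxcl13 too hold for background-corrected values only, and all 5 genes kept their calls with these intensities. Wnt2, a signalling ligand of liver endothelium, was 1.97-fold higher (log2 0.97, SE 0.12), and Cyp2d13 and the kinase gene Pim3 were 1.89- and 1.87-fold higher. Igfbp2 differed by 4.60-fold without passing (log2 2.20, SE 0.63, adjusted p = 0.196), with 3.16 and 1.25 without 12.5 ng/hr replicate 4 or 5. Scd1 differed by -0.31 (SE 0.17) without passing, and Lepr was not above background in either group.

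The stellate cell and fibroblast list was lower at 25 than at 12.5 ng/hr in all 10 members (median -0.84, adjusted p = 1.12e-07; adjusted p = 0.464 with an estimated correlation). Col1a1, Col3a1 and Lum passed over all genes, and 7 members passed when adjusted over the list alone. Male-biased genes were higher by a median of 0.71 over 13 members (adjusted p = 0.000421; adjusted p = 0.811 with an estimated correlation), none past the threshold over all genes and 5 when adjusted over the list alone, led by Elovl3 (log2 1.42, SE 0.25). Without 25 ng/hr replicate 6 the median was 0.44. Fatty acid synthesis genes were lower in all 16 members by a median of -0.34 (adjusted p = 0.000523; adjusted p = 0.811 with an estimated correlation), with Fasn, the fatty acid synthase gene, at -0.66 (SE 0.27), or -1.02 and -0.30 without 12.5 ng/hr replicate 4 or 5. No member of that list passed over all genes or adjusted over the list alone. The other 25 lists were not called (adjusted p from 0.0544 to 0.931). The macrophage list had a median of -0.04 and the endothelial list of -0.07. Single members passed when adjusted over their list alone, among them Bcl6, a transcriptional repressor gene (log2 2.26, SE 0.44), Gpnmb (log2 -3.55, SE 0.82), the apolipoprotein gene Apoa4 (log2 -1.89, SE 0.40) and Spp1 (log2 -1.47, SE 0.27). With fry the stellate list had an adjusted p of 0.0386, and the other 2 called lists did not pass.

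The count of 43 fell to 0 without 12.5 ng/hr replicate 4, to 1 without replicate 5, to 12 without 25 ng/hr replicate 6 or 7 and to 13 without replicate 8. It was 77 without background correction, 110 with the authors' scaled intensities, 17 without a detection filter and 107 with a trended prior. Median scaling gave 46 genes, 7 higher and 39 lower.

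The mean of both doses was set against the controls to ask what changes on average over the doses. A gene that changes at 1 dose only can pass, and opposite changes cancel, so sharing itself is not tested. No feature passed in limma's test, the smallest adjusted p being 0.0542 for Trim30a, while 1400 had an unadjusted p under 0.05. Other settings gave up to 149 genes, 77 passed without 25 ng/hr replicate 8 and 1 without control replicate 2. Of the 90 genes that passed at 25 ng/hr, 76 (84.4%) had the same sign at 12.5 ng/hr, and 68 of those were smaller in size there. Groups were also simulated with no effect against the same controls. The 90 genes with the smallest p then gave means of 79.6 (72 to 86 over 100 draws) and 68.7 (60 to 78), and both counts lie within these ranges. Those genes were picked on noise alone, and a change at 25 ng/hr only was not simulated. The simulation therefore does not decide how much of the agreement comes from shared controls. Across all features the fold changes of both doses correlated with r = 0.468, but simulated groups with no effect against the same controls gave r = 0.449 (0.40 to 0.50 over 100 draws). The covariance was 0.0329, above the simulated 0.0124 (0.0108 to 0.0153 over 100 draws). These draws treated genes as independent and so leave out any spread that genes share, for example from 1 unusual control. The covariance therefore does not by itself show an effect common to both doses. At an unadjusted p under 0.05, 243 genes were higher at both doses and 190 were lower at both. Lists of the same length in the simulated groups with no effect shared 214 (186 to 243 over 100 draws) and 176 (154 to 197). Neither count exceeds its simulated range, but these lists too were picked on noise alone, which leaves the part of shared controls undecided. The controls could not be split with at least 2 arrays on each side. The r of 0.468 was 0.326 without 12.5 ng/hr replicate 4 and 0.571 without control replicate 2.

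**Figure D3:**
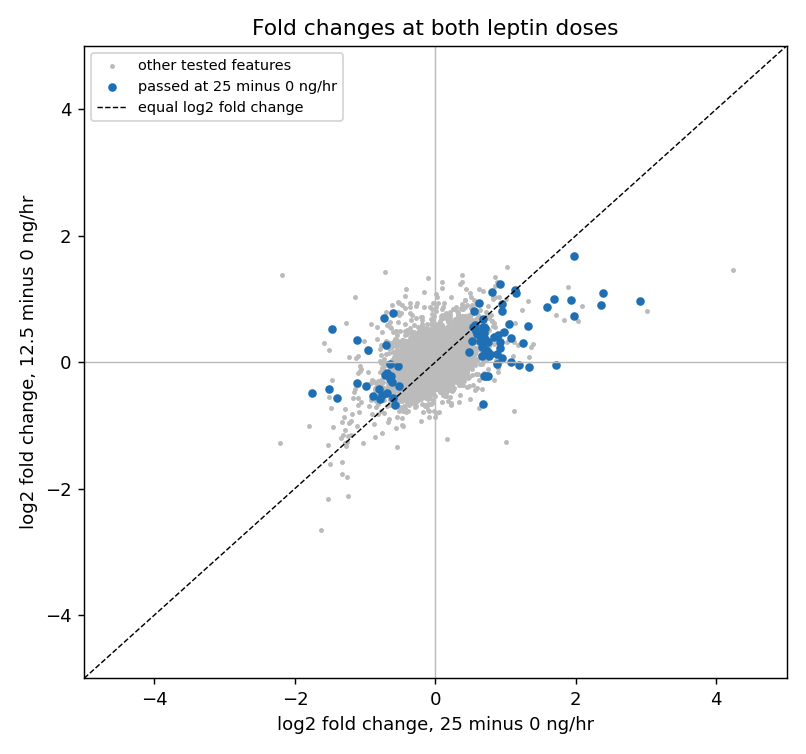
Log2 fold change at 12.5 minus 0 ng/hr (vertical axis) against that at 25 minus 0 ng/hr (horizontal axis), with 1 point per tested feature, the 90 features that passed at 25 ng/hr in blue and a dashed line of equal change. Of the 90, 76 have the same sign at both doses, a count within the range of 72 to 86 simulated with no effect at either dose. A change at 25 ng/hr only was not simulated.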

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

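The tests of the list without its Mup genes and of chip position were chosen only after the result was seen. The results below stand out because the effects of both leptin doses, each against the same controls, differed in limma's direct test of 25 minus 12.5 ng/hr.

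On the lower side at 25 ng/hr, the log2 differences between the doses were -2.01 for Emp1, -1.46 for Col6a1, -1.45 for Col3a1, -1.43 for Ccdc3, -1.38 for Lum, -1.35 for Loxl1, -1.28 for Bhlhb9, -1.27 for Fndc10, -1.15 for Slc6a8 and -1.09 for Ccdc120. Col1a1, Akr1c18 and Capn6, not above background at 25 ng/hr, were at least 3.52-, 2.14- and 2.26-fold lower there on background-corrected values. Apart from Fndc10 and Ccdc120, which were below the controls at both doses, the estimates of the genes above background lay above the controls at 12.5 ng/hr and below them at 25 ng/hr. Col3a1, for example, above background on 1 of 3 arrays at 25 ng/hr, had a log2 difference from the controls of 0.93 at 12.5 ng/hr and of -0.51 at 25 ng/hr.

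On the higher side the differences were 1.34 for H4c17, 1.08 for H4c12, 0.97 for Wnt2, 0.93 for H4c8, 0.92 for Cyp2d13, 0.90 for Pim3 and 0.88 for H4c11, and Gbp2b and Cxcl13, not above background at 12.5 ng/hr, were at least 2.75- and 1.80-fold higher on background-corrected values. Among the lists, the median differences between the doses were -0.84 for stellate cells and fibroblasts, 0.71 for male-biased genes and -0.34 for fatty acid synthesis, and with an estimated correlation none of these 3 lists was called (adjusted p = 0.464, 0.811 and 0.811).

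The stellate cell and fibroblast list had a median of 0.58 above the controls at 12.5 ng/hr and of -0.59 below them at 25 ng/hr, and its calls were lost with an estimated correlation (adjusted p = 0.811 at each dose and 0.464 between the doses). A different share of hepatocytes in the pieces of liver would move other non-parenchymal markers alike, but the endothelial list differed by a mean of -0.12 (SE 0.07) between the doses and the stellate list by -0.93 (SE 0.26), a gap of -0.81 (SE 0.24). The argument rests on the endothelial list, of whose 9 members 7 were lower at 25 than at 12.5 ng/hr. Adjusted over that list alone, 2 members passed as higher and 2 as lower, so its mean is a weak measure of cell share. The 3 cholangiocyte markers differed by a mean of -0.57 (SE 0.15), in the direction of the stellate list. Their list was not called in camera (adjusted p = 0.0731). Of these markers, Spp1 and Sox9 were lower at 25 ng/hr (log2 -1.47 and -0.42) and Krt7 was not (0.18). This decides nothing on portal tissue, whose share was not tested. A different share of stellate cells stays open as well, since the smaller difference of Lrat, Des and Reln (mean -0.41, SE 0.24) than of Col1a1, Col1a2 and Col3a1 (mean -1.52, SE 0.21) was measured against collagens of which 2 were among the leading genes and 2 not above background at 25 ng/hr. A change in collagen expression within these cells remains an untested hypothesis, and of the 43 genes that passed between the doses 0 passed without 12.5 ng/hr replicate 4 and 1 without replicate 5.

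The male-biased list was higher at 25 ng/hr than in the controls. Signal shared within the Mup family does not account for it, since the list without its Mup genes rose by a mean of 0.90 (SE 0.33) over 10 genes. A linear trend along the BeadChip would also act within the groups, where the list's slope per position was -0.24 (SE 0.15), against 0.19 between the means of the controls and the 25 ng/hr arrays. Other effects of position stay open, because each group occupies neighbouring positions. The dose of leptin may underlie the rise, which is a hypothesis found and tested on the same arrays, and the call was lost with an estimated correlation (adjusted p = 0.811).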

How the results depend on the processing

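Genes called at 25 minus 0 ng/hr (90) numbered 35 with median scaling, 192 without background correction, 189 with the authors' scaled intensities, 48 without a detection filter, 153 with detection on all arrays, 242 with a trended robust prior and 15 with only the groups compared in the fit. Median scaling also moved the share of higher calls from 70% to 57.1% there, and from 27.9% to 15.2% between the doses. At 12.5 minus 0 ng/hr (0) the counts were 9 without background correction, 10 with the authors' intensities and 35 with the trended prior, and at 25 minus 12.5 ng/hr (43) they were 77, 110 and 107 in the same order and 17 without a filter. For both doses (0) they were 80, 81 and 149 in that order, 55 with detection on all arrays, 24 with every probe as a feature, 20 with array weights and 2 with all leptin arrays as 1 group. Leaving out 1 array gave 0 to 131 genes at 25 ng/hr, 0 to 2 at 12.5 ng/hr, 0 to 60 between the doses and 0 to 77 for both doses, where a group left with 1 array was assumed to vary like the others. With fewer arrays the fit has fewer degrees of freedom. The cause of the other shifts was not tested. Of 16 called lists, camera with an estimated correlation kept 0 and fry called 3, and leaving out 1 array gave 15 to 26, the highest without 25 ng/hr replicate 8. The correlation of the doses ran from 0.326 to 0.571 when 1 array was left out.

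The 46 called results of named genes kept their sign in all settings run, and the other called genes were not followed one by one. They kept their call in 335 of 406 comparisons with other settings and in 131 of 368 without 1 array. Called lists kept their direction throughout and their call in 78 of 112 comparisons with other settings and in 118 of 128 without 1 array. None of the results changed direction while called. Signal over background limits what can be said of Col1a1, Capn6, Akr1c18, Gbp2b, Cxcl13, Trim30a and Lepr, which were at background in at least 1 group. No paired analysis was possible because the groups share no replicate number.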

Other observations

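The tests of Igfbp2 with the male-biased list and of H4 with other histone genes and the counts of other splits of the arrays were chosen only after the result was seen. The lists of interferon-stimulated, MHC class II, histone and smooth muscle genes were written after the leading genes had been seen and leave out the genes seen, apart from the H4 genes, and their 15 list tests were adjusted together.

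Genes of the interferon response that were not among the leading genes were higher at both doses. The mean log2 difference from the controls was 0.51 (SE 0.11) at 12.5 ng/hr and 0.46 (SE 0.10) at 25 ng/hr over 16 genes, with 15 and 16 of them above 0. Irf7, an interferon-inducible transcription factor gene above background on 2 of 3 control arrays, had log2 differences of 1.01 (SE 0.22) and 0.84 (SE 0.19), and Isg15, a ubiquitin-like modifier gene, of 0.54 and 0.73. In camera the adjusted p was 4.23e-09 at 12.5 ng/hr and 5.96e-08 at 25 ng/hr, and 0.0964 and 0.102 with an estimated correlation, and no single gene passed over all genes. MHC class II genes, which antigen-presenting cells express, were higher by 1.16 (SE 0.29) at 12.5 ng/hr and 0.72 (SE 0.26) at 25 ng/hr over 4 genes, among them H2-Aa (log2 1.26 and 0.88) and H2-Ab1 (log2 1.34 and 0.85). Their adjusted p was 7.51e-07 and 0.000702, and 0.12 and 0.19 with an estimated correlation. The macrophage markers of the report were also higher at both doses, though camera with an estimated correlation did not call them (adjusted p = 0.464 at 12.5 ng/hr and 0.709 at 25 ng/hr). That both groups rise with leptin at both doses is a hypothesis with smaller means of 0.46 and 0.72, but both doses were set against the same 3 controls, and low values of these controls alone could raise both.

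All 10 tested H4 histone genes lay below the controls at 12.5 ng/hr (mean -0.43, SE 0.07) and above the 12.5 ng/hr arrays at 25 ng/hr (mean 0.65, SE 0.07). Of these, 4 are the leading genes that prompted the test, the remaining 6 differed between the doses by 0.38 (SE 0.09), and the other 28 replication-dependent histone genes by 0.26 (SE 0.10), within 0.12 (SE 0.10) of those 6. At 12.5 ng/hr the 6 H4 genes differed from the controls by -0.39 (SE 0.09) and the other histone genes by -0.03 (SE 0.10). The gap was -0.37 (SE 0.10). At 25 ng/hr the 6 H4 genes differed from the controls by -0.01 (SE 0.08) and the other histone genes by 0.24 (SE 0.09). The gap there was -0.25 (SE 0.09). Only with the 4 leading genes included was the H4 mean at 25 ng/hr close to that of the other histone genes (0.22, SE 0.06). The gap at 12.5 ng/hr speaks against an equal change in all these genes as the whole cause. The gap at 25 ng/hr cannot be used for this. The 4 genes left out were chosen for their rise from 12.5 to 25 ng/hr, so leaving them out lowers the H4 mean there. Over all 10 H4 genes the gap at 25 ng/hr was -0.02 (SE 0.06). The 6 genes are no independent test, because their probes can share signal with the leading genes. A common part stays open, since both sets were higher at 25 than at 12.5 ng/hr. Between the doses camera gave adjusted p = 1.01e-09 for the 10 H4 genes, the 4 leading ones included, and 5.96e-08 for the other histone genes (24 of 28 above 0), and 0.058 and 0.16 with an estimated correlation, values that depend on how many lists written after the result are counted together. Because H4 transcripts are near-identical, the 10 probes may report a single pool of transcripts.

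Within the groups, arrays with a higher mean of male-biased genes had a lower mean of female-biased genes. Over deviations from the group means (n = 8) Pearson's r was -0.948 (exact permutation p = 0.0417, two-sided, adjusted 0.0834) and Spearman's rho was -0.952 (exact permutation p = 0.0278, adjusted 0.0556), over 72 pairings within groups. Without the 2 arrays farthest from the median of the male-biased deviations, r was -0.709. The hypothesis that both lists vary in opposite directions between livers is thus in line with the unadjusted p only. Igfbp2 and the male-biased mean had r = 0.594 (exact permutation p = 0.0972, adjusted 0.0972) and rho = 0.643 (exact permutation p = 0.125, adjusted 0.125), with r = 0.696 without the 2 farthest arrays, which leaves that relation undecided. These were the only 2 relations of the kind computed.

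The largest estimate of the series missed the threshold. Serpina1e, chosen after its values were seen, had a log2 difference of 4.23 (adjusted p = 0.0914 in limma's test) at 25 ng/hr, with values of 13.61, 11.77 and 8.54 on the 25 ng/hr arrays and 6.99 to 7.21 on the controls.

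Control replicate 1 stood apart in Acta2 and Des, which smooth muscle expresses, with log2 signals of 12.10 and 8.02. The mean of 7 other smooth muscle genes was 7.63 there and between 5.87 and 6.38 on the other 7 arrays, so it exceeded the highest of them by 1.26, where the within-group SD of the others was 0.18. That excess need not hold for each gene. The SE at 25 minus 0 ng/hr, which spread among the controls enlarges, was 1.25 for Actg2 and 0.64 for Myh11. It was 0.11 to 0.38 for the others, Tagln included (0.28). More smooth muscle in that piece of liver is a candidate explanation that goes with the higher mean, and the design gives no biological difference between control replicates to set against it. Acta2 and Des are members of the stellate cell and fibroblast list, and 30 genes passed at 25 minus 0 ng/hr without that array, 24 of them among the 90.

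Other splits of the same arrays bear on chance. The 10 splits of the 6 arrays at 0 and 25 ng/hr are too few for a share under 0.05. The real split gave 90 genes, 1 split in 10 gave as many, and the highest other gave 0. For lists adjusted within that contrast the real split gave 6, 4 of the 10 splits gave as many, and the highest other gave 11. With all leptin arrays as 1 group, 3 of 56 splits gave at least the 2 genes of the real one, so chance is not excluded, and the highest other split, which sets the 25 ng/hr arrays against the rest, gave 32. At an unadjusted p under 0.05, 2 of 56 splits gave at least the real 1271 genes, the highest other being 1522 for that same split, and as 1 of 2 counts chosen after the result was seen it does not by itself exclude chance. That split is itself a contrast of the higher dose with the other arrays.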
